A study of Mus musculus with 4 samples.

How the data were processed

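The series held 4 samples of HL-1 cells, a line of mouse atrial muscle cells that keeps beating in culture. In 2 samples the cells were paced electrically at 300 beats per minute for 24 h, which per the labels was 1.5 to 2 times the rate of the controls, and in the other 2 samples they contracted spontaneously. Total RNA was labelled with biotin and hybridised to 1 Affymetrix array per sample, an array on which each transcript is measured by 1 or more sets of short probes. The labels number both stimulated samples as experiments. Of the controls, a protocol text mentions a sample number, and the other number was given in accession order. Nothing in the labels beyond these numbers says that the samples of a group were separate cultures, so the p-values measure the spread between these samples, which may be partly technical.

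The deposited values were on the log2 scale, and per the submitters' processing notes they were made with RMA, a method that corrects background, quantile normalizes the arrays and summarises each probe set. The version and settings of RMA were not given in the sources used here, and the scanner files were not used here. The arrays had medians of 4.96 to 5.01 and values between 2.34 and 14.29. RMA compresses differences near both ends of this range, so the change of a gene near the bottom or the top can be understated. The number of arrays, 2 per group, limits the precision.

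The table held 45101 probe sets, of which 64 were the manufacturer's controls. Of the other 45037, 34945 had 1 gene symbol in the annotation used, 932 had several and 9160 had none. The gene identifiers of 34741 of the probe sets with 1 symbol were found in a RefSeq gene table of the mouse assembly GRCm38.p6, used only for names, and 0 symbols needed updating. No coordinates were used. Each of the 18193 genes was represented by the probe set with the highest mean over the 4 arrays among those with exactly 1 symbol. Genes whose mean reached the 40th percentile of all probe sets, 4.39 on the log2 scale, were kept, which left 13058 genes. For each gene named in the text, the changes of its other probe sets past the same level are given, as values or as lowest and highest, where any of them differed by over 0.5 from that of the probe set used.

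Stimulated and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 13058 genes and a threshold of 0.05. A gene called higher or lower, or said to have risen or fallen, passed this threshold. Changes are stimulated minus control on the log2 scale, with the standard error of the fit. Levels are means ± SD of 2 arrays. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, so no single gene was tested that way.

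Before the data were examined, 33 gene lists were written from general knowledge, with 917 genes. Of these, 827 had a probe set with 1 symbol and 729 were tested. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 33 lists. Beside it, camera was run with the correlation estimated from the data, and fry, which tests whether the genes of a list move one way on balance (directional) or in either direction (mixed). Calls of list members were counted over all genes tested and also adjusted over the list alone. Some genes stand in more than 1 list, among them Acta1, Ccn2, Tbx3 and Sesn2. The lists were hypertrophy and fetal cardiac genes, calcium handling, potassium channels, sodium and pacemaker channels, gap junction and intercalated disc, sarcomere, cardiac transcription factors and calcineurin signalling, immediate early genes, heat shock proteins, endoplasmic reticulum chaperones, ATF4 amino acid response, oxidative stress response, NADPH oxidase with nitric oxide and RAC1, oxidative phosphorylation, fatty acid use, glycolysis, hypoxia response, cholesterol synthesis, extracellular matrix and TGF-beta, inflammatory mediators, interferon response, cell cycle, p53 targets and apoptosis, calpain with atrophy and autophagy, proteasome, neurohumoral receptors and signalling, circadian clock, cytosolic ribosomal proteins, and markers of fibroblasts, smooth muscle, endothelium, leukocytes, and the ventricle and conduction system.

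The genes named in the text were chosen by a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among called genes whose stimulated arrays both lay on the same side of both control arrays, leaving out clone names. It also took the 4 members of each list with the smallest p, and a short set of atrial genes (Nppa, Nppb, Myh6, Myh7, Cacna1c, Kcna5, Kcnj3, Kcnj5, Gja1, Gja5, Atp2a2, Ryr2, Ace and Hspa1b). Some listed genes had no probe set with 1 symbol in the annotation used and are not analysed here. Hopx, Hey1, Pfkfb3, Capn2, Tex19.2, Tfrc and the genes that the closing section names as ribosome assembly factors were chosen after their values were seen.

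The steps were tested on simulated data made from the means and spread of the 13058 genes, with 200 genes changed in each of 10 runs. The test recovered 0.606% of genes changed by 0.5 on the log2 scale, 44.2% of those changed by 1 and 95.2% of those changed by 2. Mean estimates were 0.50, 0.99 and 2.00. Of all calls, 4.67% were false, and 4.94% of unchanged genes had an unadjusted p under 0.05. A list shifted by 0.5 was called in 10 of 10 runs, and 0 of 320 unshifted lists were called by camera. The simulated genes were independent of each other, so this does not cover lists whose members vary together.

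The alternatives were no filter, a filter at the 60th percentile, a second quantile normalization, centring of each array on its median, a floor at the 20th percentile, a trended and robust eBayes fit, the mean of all probe sets of a gene, leaving out probe sets that can cross-hybridise, every probe set in place of 1 per gene, an adjusted p under 0.1, limma's treat against a fold of 1.2, the experiment number as a block, and leaving out each array in turn.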

Results

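The series measured mRNA in HL-1 mouse atrial muscle cells that were either paced rapidly for 24 h (2 arrays) or left to contract spontaneously (2 arrays). The comparison asks how the transcripts of atrial cells differ after a day of pacing at 1.5 to 2 times the rate of the controls. No group was stimulated at the control rate, so effects of the faster rate and of the electrical stimulation itself cannot be told apart. Across the 13058 genes tested, the 2 control arrays correlated at r = 0.992 and the 2 stimulated arrays at r = 0.989, and arrays of different groups correlated at 0.968 to 0.975. These correlations are across genes, which are not independent replicates. The SD of the difference between arrays was 0.25 within the controls, 0.30 within the stimulated samples and 0.46 to 0.52 between groups.

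With rapid stimulation Nppb, which encodes brain natriuretic peptide, rose from 5.92 ± 0.60 to 13.05 ± 0.07 (SD, n = 2). This was a rise of 7.13 ± 0.27 (SE) on the log2 scale or 140.1-fold (adjusted p = 0.00138). Nppa, the atrial natriuretic peptide gene, was already high in control cells at 10.82 ± 0.20 and rose by 2.00 ± 0.14 (adjusted p = 0.00561). The inducible heat shock protein genes Hspa1a and Hspa1b rose by 8.29 ± 0.40 and 5.19 ± 0.23, and Acta1, skeletal muscle alpha-actin, by 3.62 ± 0.15. Gja5, the gap junction protein connexin 40, fell by 2.40 ± 0.30, from 7.20 ± 0.55 to 4.81 ± 0.40 (adjusted p = 0.0228). Bnip3, a mitochondrial protein of the hypoxia response, fell by 2.51 ± 0.37, from 10.75 ± 0.85 to 8.23 ± 0.15 (adjusted p = 0.0294).

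In all, 722 genes passed the test, 510 higher and 212 lower with stimulation, so that 70.6% of the calls were rises. With each array centred on its median, 55.3% of 852 calls were rises. Changes of 2-fold or more made up 243 of the rises and 66 of the falls, and changes of 4-fold or more 48 and 6. At an unadjusted p under 0.05 there were 3338 genes, where chance gives 652.9. The arrays of the groups did not overlap in any of the 722 genes. Among all genes tested, 55.3% did not overlap, where chance gives 33.3%. Each left-out array moved the count strongly: 70 genes passed without stimulated 1, 113 without stimulated 2, 40 without control 1 and 20 without control 2. Of the 722 genes, those that passed in all 4 fits were all rises. Among them were Hspa1a, Nppb, Hspa1b, Tex19.1, Ryr1, Acta1, Fgf21, Gadd45a, Ddit3, Cth and Nppa. The falls, Gja5 and Bnip3 among them, did not pass in all 4 fits.

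Tex19.1, a germline gene, rose by 5.01 ± 0.28 (adjusted p = 0.00302), and its paralog Tex19.2 by 2.27. Ryr1, the skeletal muscle calcium release channel, rose by 4.55 ± 0.29 from a control level of 3.94 ± 0.36 that lay below the filter level (adjusted p = 0.00424). A second Ryr1 probe set, below the filter, differed by 0.07. The stress transcription factor gene Atf3 rose by 3.82 ± 0.47, Fgf21, a secreted metabolic hormone, by 3.53 ± 0.12, and Gadd45a, a growth arrest gene, by 3.19 ± 0.17. The matricellular genes Ccn1 and Ccn2 rose by 3.36 ± 0.36 (other probe sets of Ccn1 2.26 to 3.69) and 3.16 ± 0.39. Efr3b rose by 3.10 ± 0.41, but its other probe set past the filter differed by -0.15. Hspa1a and Hspa1b are nearly identical in sequence, so their probe sets may not separate them. Hspa1a lay below the filter level in control cells, at 3.73 ± 0.44.

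**Figure D1:**
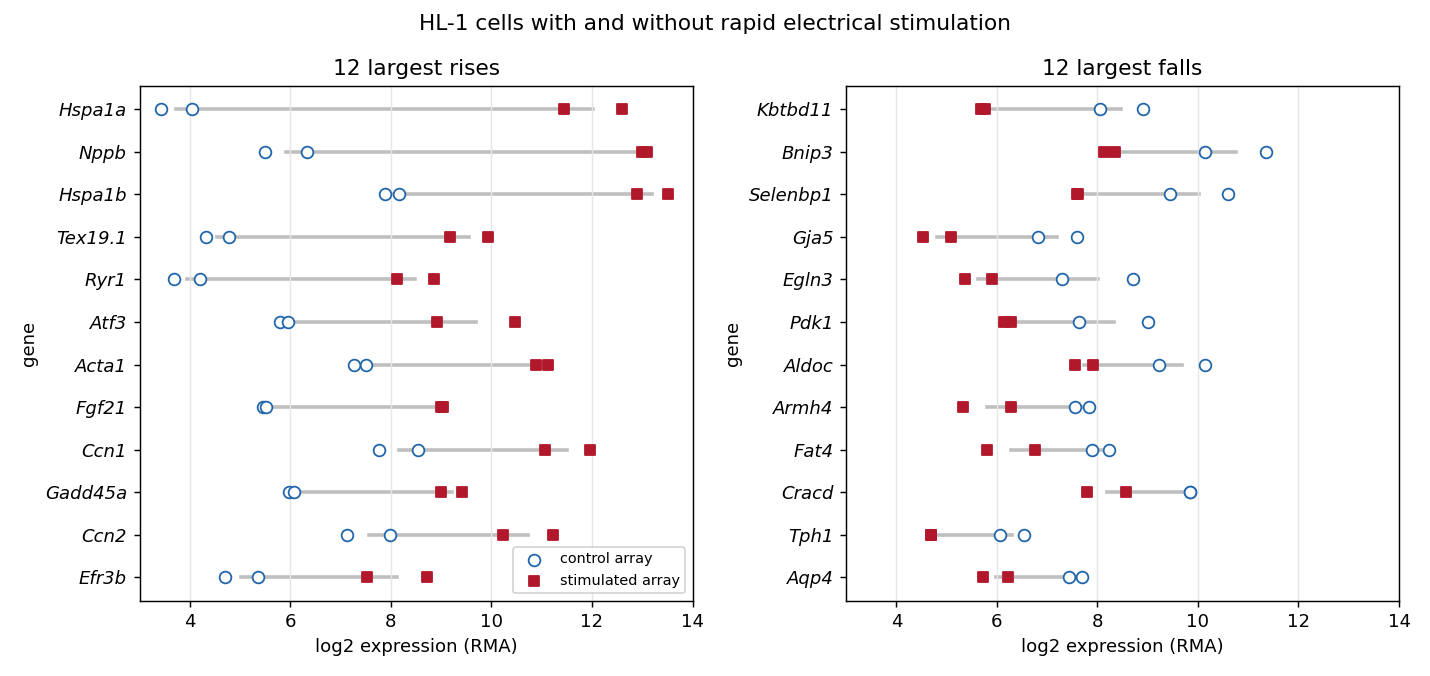
Log2 expression of the genes with the largest rises and the largest falls on each array. Points are the 2 control and the 2 stimulated arrays. Nppb has a mean of 5.92 on the control arrays and of 13.05 on the stimulated arrays.

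Among the falls, Kbtbd11 fell by 2.76 ± 0.27 (its other probe sets changed by -1.25 and -0.82), and the selenium-binding protein gene Selenbp1 fell by 2.41 ± 0.35. Egln3, an oxygen-sensing prolyl hydroxylase, fell by 2.38 ± 0.45 (other probe set -1.18). Pdk1, an inhibitor of pyruvate dehydrogenase, fell by 2.11 ± 0.42 (other probe sets -3.24 and -2.36), and Aldoc, a glycolytic aldolase, fell by 1.94 ± 0.31. Armh4 fell by 1.89 ± 0.31, the cadherin gene Fat4 fell by 1.78 ± 0.32, and the water channel gene Aqp4 fell by 1.59 ± 0.20 (other probe sets -1.94 and -1.01). Tph1, which encodes a tryptophan hydroxylase, fell by 1.63 ± 0.18, and both stimulated arrays read 4.68. Cracd fell by 1.65 ± 0.25, but its other probe sets differed by -0.15 and -0.01. Adjusted p for these genes lay between 0.0149 and 0.047.

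Of the 33 lists, 18 shifted by camera, 7 up and 11 down. With the correlation estimated from the data 0 lists passed: 2 had an unadjusted p under 0.05, the lowest adjusted p was 0.462, and among the 18 lists it reached 0.625. By fry 0 lists passed in the directional test (13 at an unadjusted p under 0.05, lowest adjusted p = 0.0669) and 21 in the mixed test. All list shifts below therefore rest on the preset correlation. With 2 arrays per group, camera with an estimated correlation and directional fry had little power to call a list after adjustment. Their 0 therefore does not decide whether the lists shifted.

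**Figure D2:**
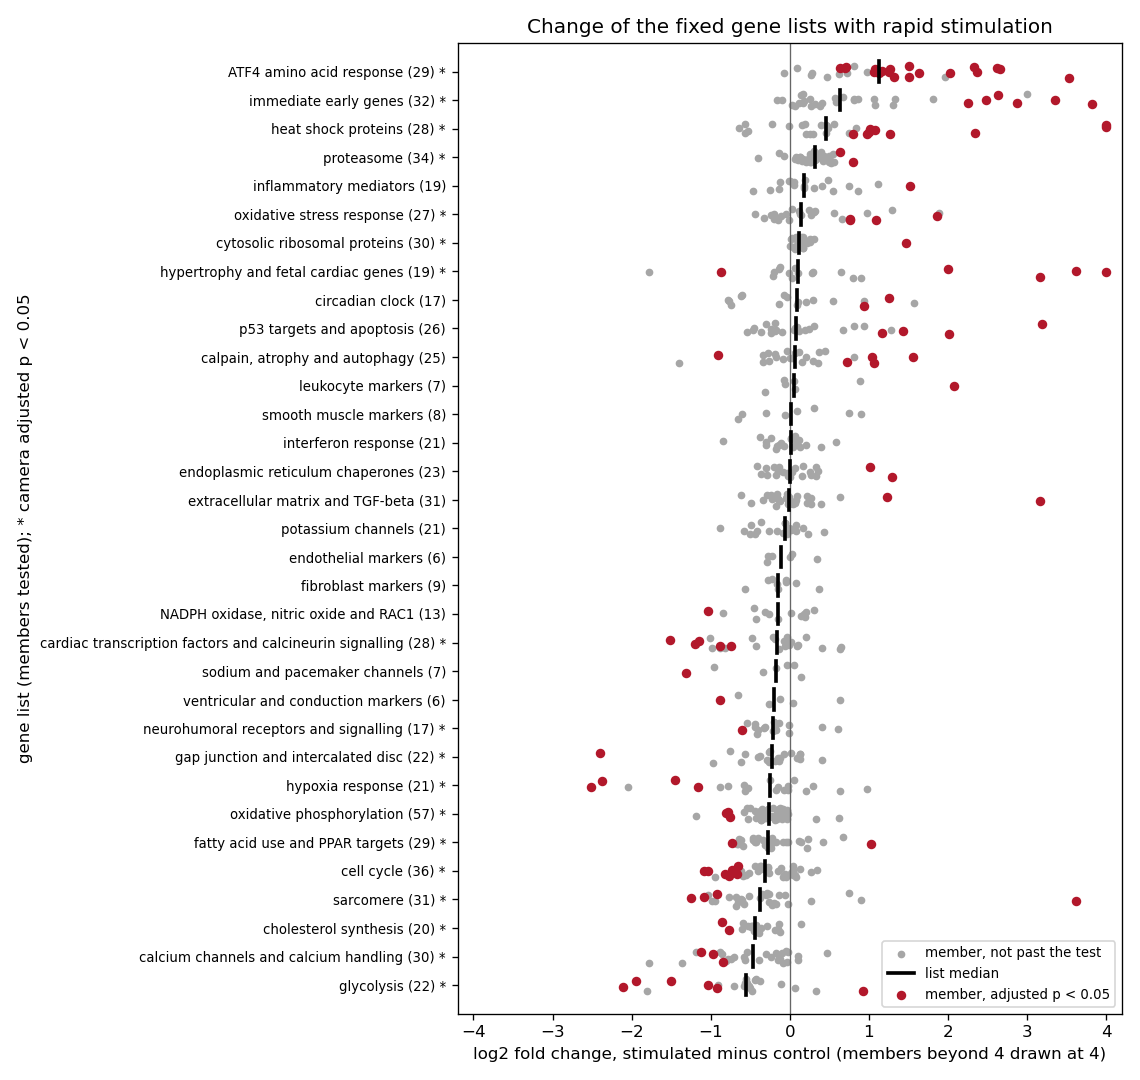
Changes of the tested genes of each list, stimulated minus control on the log2 scale, with the list's median. The ATF4 amino acid response has the highest median, 1.12, and glycolysis the lowest, -0.55.

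Genes of the ATF4 amino acid response, which are induced when protein synthesis is restrained under stress, shifted up as a list. Of 29 tested, 19 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 1.12. Fgf21, the stress factor Ddit3 (2.62 ± 0.13, other probe set 1.30), the cysteine-making enzyme Cth (2.03 ± 0.15) and the pseudokinase Trib3 (2.66 ± 0.22) had the smallest p. The list's adjusted p was 5.45e-18, and adjusted p = 0.462 with an estimated correlation. The endoplasmic reticulum chaperone list did not shift (median 0.01, adjusted p = 0.634, and adjusted p = 0.763 with an estimated correlation). Of its 23 genes, Herpud1 (1.02 ± 0.16) and Dnajb9 (1.29 ± 0.25) rose and 0 fell (2 and 0 adjusted over the list alone), while Pdia4 changed by -0.41 (adjusted p = 0.109) and Atf6 by 0.33 (adjusted p = 0.162).

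Heat shock protein genes shifted up (28 tested, median 0.46, adjusted p = 7.71e-06, and adjusted p = 0.462 with an estimated correlation). Of these, 9 rose and 0 fell (13 and 4 adjusted over the list alone, the 4 being Hspb2 at -0.64, Dnajb4 and Hspb3 at -0.57 and Hspb6 at -0.52). Besides Hspa1a and Hspa1b the rises included the small heat shock protein genes Hspb1 (1.08 ± 0.12) and Cryab (1.01 ± 0.12). Hspb1 stood at 14.29 on both stimulated arrays, the highest value of any probe set. The median of the heat shock list was 0.31 without stimulated 2 and 0.57 without stimulated 1. Immediate early genes, which respond quickly to stimuli, also shifted up (32 tested, median 0.63, adjusted p = 2.32e-07, and adjusted p = 0.462 with an estimated correlation). Among them 6 rose and 0 fell (15 and 0 adjusted over the list alone). The rises included Atf3, Ccn1, Gadd45b (2.48 ± 0.22, other probe sets 0.40 and 2.91) and Fosl1 (2.63 ± 0.35, other probe set 1.02). The median of the immediate early list was 0.43 without stimulated 2 and 0.82 without stimulated 1. The proteasome list shifted up by a median of 0.32, with 31 of 34 genes higher (adjusted p = 3.88e-06, and adjusted p = 0.462 with an estimated correlation). Only Psmd11 (0.80 ± 0.13, other probe sets 0.10 to 0.85) and Psmc4 (0.64 ± 0.12) rose over all genes tested and 0 fell (11 and 1 adjusted over the list alone), while Psmd12 changed by 0.55 and Psmd14 by 0.54 (both adjusted p = 0.0606). The oxidative stress list shifted up (27 tested, median 0.14, adjusted p = 0.0351, and adjusted p = 0.462 with an estimated correlation), with 4 rises, Osgin1 (1.86 ± 0.24), Srxn1 (1.09 ± 0.18, other probe sets 0.03 to 1.01), Cat (0.77 ± 0.13, other probe set 0.30) and Gclc (0.75 ± 0.14), and 0 falls (9 and 1 adjusted over the list alone). The shift was lost without stimulated 2 (median 0.27, adjusted p = 0.0881) and without control 1 (median 0.06, adjusted p = 0.0798), and the median was 0.24 without control 2. Cytosolic ribosomal protein genes were all higher, 30 of 30, by a median of 0.12 (adjusted p = 0.0151, and adjusted p = 0.462 with an estimated correlation). Only Rpl12 rose singly (1.47 ± 0.25, with 1 up and 0 down adjusted over the list alone), while Rps18 changed by 0.31, Rpl10a by 0.26 and Rps3 by 0.26. The Rpl12 probe set read only 6.11 ± 0.31 in controls, against 13.26 for Rps18, 12.83 for Rpl10a and 12.72 for Rps3. The shift of the ribosomal protein list was lost without stimulated 2 (median 0.10) and without control 1 (median 0.11), though the medians moved little.

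The hypertrophy and fetal cardiac list shifted up (19 tested, median 0.11, adjusted p = 0.0227, and adjusted p = 0.509 with an estimated correlation). Nppb, Acta1, Nppa and Ccn2 rose, and the cardiac cofactor gene Hopx fell by 0.87 ± 0.16 (6 up and 2 down adjusted over the list alone). Without stimulated 2 the shift was lost (adjusted p = 0.268), and the median was 0.33 without stimulated 1, 0.21 without control 1 and 0.17 without control 2. Myh7 lay below the filter level, at a mean of 4.10 over the 4 arrays. Sarcomere genes shifted down (31 tested, median -0.37, adjusted p = 9.22e-05, and adjusted p = 0.545 with an estimated correlation). Acta1 rose, while Smyd1 (-1.08 ± 0.15, other probe sets -1.0 to -0.0027), Nebl (-1.25 ± 0.23, other probe sets -2.24 and -1.35) and Tmod1 (-0.92 ± 0.19) fell, and 3 rose and 13 fell adjusted over the list alone. Without stimulated 2 the list's median was -0.58, and without stimulated 1 it was -0.31. Myh6, the main myosin heavy chain of the atrium, changed by -1.03 ± 0.30 (adjusted p = 0.0998), and by -2.89 on its other probe set. Its stimulated arrays differed, at 11.25 and 12.19, against 12.75 ± 0.06 in controls.

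Calcium channel and calcium handling genes shifted down (30 tested, median -0.47, adjusted p = 5.62e-06, and adjusted p = 0.462 with an estimated correlation). Of these 3 fell and 0 rose (13 and 0 adjusted over the list alone): Trdn, triadin (-1.12 ± 0.19), Ryr2, the cardiac calcium release channel (-0.85 ± 0.16), and the channel subunit gene Cacnb2 (-0.98 ± 0.19). Hrc changed by -0.88 (adjusted p = 0.0577), Cacna1c by -0.39 (adjusted p = 0.124) with -1.08 on its other probe set, and Atp2a2, the sarcoplasmic calcium pump, by -0.10 (adjusted p = 0.68) with -0.60 to -0.05 on its other probe sets. Cardiac transcription factors and calcineurin signalling genes shifted down (28 tested, median -0.16, adjusted p = 0.00297, and adjusted p = 0.462 with an estimated correlation). Tbx5 (-1.51 ± 0.21, other probe set -0.78), Hand2 (-1.15 ± 0.18), Hey1 (-1.19 ± 0.22), Tbx3 (-0.88 ± 0.13, other probe sets -1.34 to -0.10) and Gata4 (-0.74 ± 0.13) fell and 0 rose (11 and 2 adjusted over the list alone). Of the members of the sarcomere, calcium and transcription factor lists, 26 of middle brightness were taken as mainly expressed in muscle. This set was chosen after the values were seen, and some members, such as Tbx5, Hand2, Tbx20 and Ryr2, are also expressed in other tissues. The median of the 26 was -0.79, and 7 of them, Acta1 included, differed from it at an unadjusted p under 0.05. Gap junction and intercalated disc genes shifted down (22 tested, median -0.22, adjusted p = 0.009, and adjusted p = 0.462 with an estimated correlation). Only Gja5 fell and 0 rose (2 and 0 adjusted over the list alone). Gja1, connexin 43, changed by -0.98 (adjusted p = 0.0606, other probe set -0.31), Cdh2 by -0.62 and Cav3 by -0.76. The Gja1 probe set read only 5.47 ± 0.37 in controls and 4.49 ± 0.26 in stimulated cells, near the filter level of 4.39.

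Potassium channel genes did not shift (21 tested, median -0.06, adjusted p = 0.131), and 0 members passed in either count. They passed as a list, downward, with the 60th percentile filter (median -0.31, adjusted p = 0.0315) and with the mean of all probe sets (median -0.25, adjusted p = 0.039). The acetylcholine-gated channel genes Kcnj5 and Kcnj3 changed by -0.88 (adjusted p = 0.0601, other probe set -1.64) and -0.50 (adjusted p = 0.113), Kcnn1 by -0.49 and Kcnj4 by 0.43. Kcna5 lay below the filter level, at a mean of 2.96. Sodium and pacemaker channel genes did not shift (7 tested, median -0.17, adjusted p = 0.0925), though Scn10a, a sodium channel gene, fell by 1.31 ± 0.23 (2 down and 0 up adjusted over the list alone). The list passed with the mean of all probe sets (median -0.31, adjusted p = 0.0486). Fxyd1 changed by -0.96, Atp1b1 by -0.34 and Hcn2 by -0.17.

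Glycolysis genes shifted down (22 tested, median -0.55, adjusted p = 1.22e-06, and adjusted p = 0.462 with an estimated correlation). The enzyme genes Pfkl (-1.50 ± 0.23, other probe sets -1.59 and -0.43), Aldoc, Ldha (-1.03 ± 0.17) and Tpi1 (-0.92 ± 0.15) and the kinase gene Pdk1 fell, and Pfkfb3, a regulator of glycolytic flux, rose by 0.92 ± 0.18, with -0.17 on its other probe set (17 down and 1 up adjusted over the list alone). Hypoxia response genes shifted down (21 tested, median -0.25, adjusted p = 0.0072, and adjusted p = 0.625 with an estimated correlation). Bnip3, Egln3, Adm (-1.45 ± 0.25) and Egln1 (-1.16 ± 0.22) fell and 0 rose (7 and 0 adjusted over the list alone). That shift was lost without control 2 (median -0.05, adjusted p = 0.21) and without stimulated 1 (adjusted p = 0.0511), and its median was -0.74 without control 1 (adjusted p = 1.31e-08). Oxidative phosphorylation genes were lower in 55 of 57 cases, with a median of -0.26 (adjusted p = 2.83e-07, and adjusted p = 0.509 with an estimated correlation). Sdhd (-0.76 ± 0.15), Ndufb3 (-0.80 ± 0.16) and Cox8b (-0.78 ± 0.14) fell and 0 rose (3 and 0 adjusted over the list alone), while Cox7a1 changed by -0.59. Fatty acid genes shifted down (29 tested, median -0.27, adjusted p = 0.00297, and adjusted p = 0.462 with an estimated correlation). Acadm, which oxidises medium-chain fatty acids, fell by 0.73 ± 0.14 and the thioesterase gene Acot2 rose by 1.02 ± 0.12, with 0.26 on its other probe set (8 down and 2 up adjusted over the list alone), while Hadh changed by -0.62 and Ppargc1a by -0.65 (other probe sets -0.31 to -0.13). Cholesterol synthesis genes shifted down (20 tested, median -0.44, adjusted p = 3.15e-06, and adjusted p = 0.462 with an estimated correlation). Nsdhl (-0.86 ± 0.17) and Stard4 (-0.77 ± 0.12) fell and 0 rose (9 and 0 adjusted over the list alone), while Fdps changed by -0.61 and Hmgcs1 by -0.59. Without stimulated 1 the list's median was -0.28.

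Cell cycle genes shifted down (36 tested, median -0.31, adjusted p = 7.71e-06, and adjusted p = 0.462 with an estimated correlation). Of these 7 fell and 0 rose (12 and 0 adjusted over the list alone), including the mitotic genes Plk1 (-1.09 ± 0.16), Cenpe (-0.82 ± 0.13, other probe set -1.36), Cenpa (-1.03 ± 0.17, but 0.21 on its other probe set) and Ccna2 (-0.74 ± 0.12). The p53 and apoptosis list did not shift (26 tested, median 0.08, or 0.03 to 0.14 with 1 array left out, adjusted p = 0.196), but Gadd45a, Bid (2.01 ± 0.19, other probe set 1.22), Plk3 (1.43 ± 0.15) and Sesn2 (1.17 ± 0.18) rose and 0 fell (6 and 0 adjusted over the list alone). The calpain, atrophy and autophagy list did not shift (25 tested, median 0.06, or 0.01 to 0.11 with 1 array left out, adjusted p = 0.254). The autophagy genes Sqstm1 (1.56 ± 0.14, other probe set 0.58), Gabarapl1 (1.06 ± 0.13) and Atg12 (1.04 ± 0.16) rose, as did the calpain gene Capn2 (0.72 ± 0.12), and Atg7 (-0.91 ± 0.15, other probe sets -0.44 and -0.40) fell (5 up and 1 down adjusted over the list alone). The circadian list did not shift (17 tested, median 0.10, or -0.02 to 0.09 with 1 array left out, adjusted p = 0.609), though Per1 (1.26 ± 0.14) and Cry2 (0.94 ± 0.14) rose and 0 fell (5 and 4 adjusted over the list alone), while Per3 changed by -0.60 and Bhlhe40 by -0.78.

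Neurohumoral receptor and signalling genes shifted down (17 tested, median -0.21, adjusted p = 0.0198, and adjusted p = 0.462 with an estimated correlation). Only Nr3c1, the glucocorticoid receptor gene, fell (-0.61 ± 0.12) and 0 rose (1 and 0 adjusted over the list alone), while Edn1, endothelin 1, changed by 0.61, Ace by -0.21, Grk5 by -0.42 and Adcy6 by -0.41. The shift was lost without stimulated 1 (adjusted p = 0.0957) and without control 2 (adjusted p = 0.0755), and its median was -0.38 without stimulated 2. The NADPH oxidase, nitric oxide and RAC1 list did not shift (13 tested, median -0.15, adjusted p = 0.17). It passed without control 2 (median -0.13, adjusted p = 0.0457) and with the 60th percentile filter (median -0.37, adjusted p = 0.00846), and its median was -0.27 without stimulated 1, -0.06 without stimulated 2 and -0.01 without control 1. Gucy1a1, a subunit of the nitric oxide receptor, fell by 1.04 ± 0.14 (other probe sets -1.82 and -1.77) and 0 rose (4 and 0 adjusted over the list alone), while Ddah2 changed by -0.46, Prkg1 by -0.84 (other probe set -0.32) and Rac1 by -0.43. Inflammatory mediators did not shift (19 tested, median 0.18, adjusted p = 0.0549). They passed without stimulated 2 (median 0.25, adjusted p = 0.00746), with no filter (median 0.09, adjusted p = 0.0314) and with median centring (median 0.12, adjusted p = 0.0383), and their median was 0.09 without stimulated 1. The chemokine gene Cxcl10 rose by 1.53 ± 0.20 and 0 fell (4 and 0 adjusted over the list alone), while Relb changed by 1.12 (adjusted p = 0.0502), Nfkb2 by 0.75 (other probe set 0.16) and Icam1 by 0.86. The interferon list did not shift (21 tested, adjusted p = 0.478), its median of 0.01 and mean of -0.05 differed in sign, with the test's direction down, and 0 members passed in either count. Usp18 changed by -0.84, B2m by 0.39, Ifit2 by -0.38 and Psmb8 by -0.30. The extracellular matrix and TGF-beta list did not shift (31 tested, adjusted p = 0.906), with a median of -0.01 against a mean of 0.12 and the test's direction up. Ccn2 and Timp3, an inhibitor of matrix proteases, rose (1.23 ± 0.24 for Timp3) and 0 fell (2 and 0 adjusted over the list alone), while Tgfbr1 changed by 0.64 (other probe set 0.02) and Col6a2 by -0.61.

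Markers of other cell types did not shift as lists. Fibroblast markers had a median of -0.15 over 9 genes (adjusted p = 0.453) and 0 calls in either count, with Vim at -0.56, Ddr2 at 0.37, Tcf21 at -0.28 and Dcn at -0.17. Smooth muscle markers had a median of 0.01 over 8 genes (adjusted p = 0.872) and 0 calls (2 up and 1 down adjusted over the list alone), with Des at 0.75 (other probe set -0.10), Tagln at 0.90, Smtn at -0.60 and Mylk at -0.66. Endothelial markers had a median of -0.11 over 6 genes, or -0.14 to -0.05 with 1 array left out (adjusted p = 0.599) and 0 calls in either count, with Esam at 0.34, Kdr at -0.29, Egfl7 at -0.27 and Flt1 at -0.23. Leukocyte markers had a median of 0.05 over 7 genes, or -0.0047 to 0.10 with 1 array left out (adjusted p = 0.478), and Cd68, a lysosomal protein of macrophages, rose by 2.08 ± 0.23 from the filter level (1 up and 0 down adjusted over the list alone), while Csf1r changed by 0.89 (other probe sets 0.09 and 0.30), Adgre1 by -0.32 and Cd3e by 0.07. Ventricular and conduction markers had a median of -0.19 over 6 genes (adjusted p = 0.257), -0.35 without control 1 and -0.05 without control 2. Tbx3 fell and 0 rose (2 down and 1 up adjusted over the list alone), while Shox2 changed by 0.63 (other probe set -0.0026), Myl2 by -0.65 and Irx3 by -0.27. The manufacturer's probe sets for 18S ribosomal RNA were on average 0.86 higher on the stimulated arrays, though none of them passed limma's test over all probe sets. The poly-A spikes were 0.97 higher on stimulated 2 than the mean of the other 3 arrays.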

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

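In this part, the tests of compression, of HIF activity, of other cell types and of the share of muscle cells were chosen after the results they measure were seen. The limits that would decide the last 2 were also set after their values were seen.

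Among the manufacturer's control probe sets, which the gene comparisons did not use, the 18S ribosomal RNA sets were 0.86 higher on the stimulated arrays, at 9.24 against 8.38. The control arrays themselves read 8.71 and 8.05. None of these sets passed limma's test over all probe sets (adjusted p = 0.0551 to 0.456). The B1 repeat set was 0.23 higher on the stimulated arrays (adjusted p = 0.473 by the same test). The B2 repeat sets were on average 0.37 higher, at 0.60 and 0.14 (adjusted p = 0.139 and 0.646). The poly-A spikes, added to the RNA before labelling, lay 0.97 above the mean of the other 3 arrays on stimulated 2 (8.66 against 7.65, 7.70 and 7.73). Of the 3738 probe sets past the filter without a single gene symbol, 63 were called higher and 32 lower.

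The ATF4 amino acid response list shifted up, with 19 of 29 members called higher, while the endoplasmic reticulum chaperone list did not shift, and the medians differed by 1.12. The ATF4 call was lost with an estimated correlation (adjusted p = 0.462). Compression of bright signals is argued against as the whole cause, since the 9 ATF4 members at least as bright in controls as the median chaperone had a median of 0.70, but a part in it stays open. A single array as the source is argued against too, since the lowest of the 4 array-pair differences was 0.88 and the highest 1.26. A response of the eIF2alpha-ATF4 branch apart from the chaperones stays open, since comparing the lists that show the pattern cannot decide it.

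The 43 hypoxia response and glycolysis genes had a median of -0.53. The lowest median of 10000 random lists matched on mean level was -0.25, which argues against a general fall of genes of this brightness. The 43 genes' own median lay at percentile 0 of these lists. That percentile cannot show that they fell as a group, since their lists were taken up because they had fallen. Differences between dishes, such as oxygen or density, stay open and could account for much of the fall. The controls differed from each other by 0.42 in these genes' median, 0.778 of the difference between groups. Lower HIF activity also stays open, with 76.2% of the hypoxia list negative and its call lost with an estimated correlation, a test with little power here.

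The calcium handling, sarcomere and cardiac transcription factor lists (89 genes, Acta1 among them, median -0.36) shifted down, with 3, 3 and 5 members called lower, while Nppa, Nppb and Acta1 rose. These list calls were lost with an estimated correlation (adjusted p = 0.462, 0.545 and 0.462). A single array is argued against, since the 4 array-pair medians lay between -0.49 and -0.26. The 22 markers of fibroblasts, endothelial cells and leukocytes had a median of -0.056 (exact 95% interval -0.23 to 0.07), with Cd68 the 1 called higher. Several of these markers, such as Dcn, Tcf21, Adgre1 and Esam, lay near the filter level in controls, where a change can be understated. Their median therefore does not decide whether such cells took a larger share. A smaller share of differentiated cells within the line stays open for the falls, though not for the rises. Of 26 members taken as mainly expressed in muscle and of middle brightness (Acta1 included, median -0.79), 7 differed from that median (26.9%, exact 95% interval 11.6 to 47.8). Of these 6 lay above it and 1, Tbx5, below. Both exact intervals, of the markers and of this share, are across genes. Genes are not independent replicates, so the intervals do not measure the spread between samples. A plain limit of 20% would have excluded this explanation, but some members are also expressed outside muscle, which weakens the test. A program of lower cardiac gene expression beside the natriuretic peptides stays open too, since comparing the lists that show the pattern cannot decide it.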

How the results depend on the processing

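All alternatives here were planned before the data were examined. The count of 722 genes (510 higher, 212 lower) stayed within 1.5 times under 9 settings, from 643 (no filter) to 1039 (every probe set). The falls alone moved further, to 319 with the 60th percentile filter, 381 with median centring and 328 with the trended robust fit. Every probe set gave 373, counted over 27022 probe sets and not over 13058 genes. Median centring moved the median change of all genes from -0.0056 to -0.068, which by construction moves calls towards falls. For the filter and the trended robust fit the cause was not tested. An adjusted p under 0.1 gave 1800 (1087 and 713) and treat against a fold of 1.2 gave 136 (125 and 11), by the construction of those thresholds. Leaving out 1 array gave 20 to 113 genes, 19 to 72 higher and 0 to 41 lower. These fits have fewer samples, and assume that the lone array of a group varies like the other group. The floor raised 5 values of tested genes and says nothing. The 18 list shifts became 0 with an estimated correlation and 0 with directional fry, whose construction allows for genes that vary together. With 2 arrays per group both tests have little power, so the loss does not show that genes varying together made the shifts. The direction of camera's test turned in lists that had not passed. With the mean of all probe sets this held for extracellular matrix (median 0.026) and fibroblast markers (median -0.044). Leaving out 1 array also turned it, with medians from -0.036 to 0.10 for extracellular matrix, -0.14 to 0.036 for interferon, 0.0042 to 0.042 for chaperones, -0.24 to 0.12 for fibroblast markers and -0.10 to 0.078 for smooth muscle markers. Over the same fits Mylk lay between -1.33 and 0.014 and Irx3 between -0.59 and 0.060, neither of them called. The cause of these turns was not tested. Of the 82 calls among the 144 named genes, leaving out stimulated 1 ended 64, stimulated 2 60, control 1 61 and control 2 68, averaging probe sets ended 11, no filter 6, leaving out cross-hybridising probe sets 3 and median centring 1. Calls were gained with the block (17), the 60th percentile filter (11), the trended robust fit (10), median centring (9), averaging (8), the second quantile normalization (6) and without stimulated 2 (2). Lists that had not passed did so with the 60th percentile filter (potassium channels, NADPH oxidase), averaging (potassium, sodium and pacemaker channels), no filter and median centring (inflammatory mediators), without control 2 (NADPH oxidase) and without stimulated 2 (inflammatory mediators). Signal over background limits genes near 4.39.

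With the experiment number as a block (the replicate block), 1345 genes passed, 856 higher and 489 lower, including all 722. The numbers are shared only as numbers, and deviations of same-numbered arrays correlated at 0.334, so this is a hint from the data, not the design. The block also made the inflammatory list pass (adjusted p = 0.0442) and ended no list shift. Splitting the arrays by experiment number called 0 genes (334 at an unadjusted p under 0.05 by limma), and the crossed split 0 (27). Both splits put a stimulated and a control array on each side, so the group difference widened the spread. Both counts lay below the 652.9 that chance gives, so these splits cannot tell whether the experiments differed.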

Other observations

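The test here was written before the values of its genes were seen, but the idea came from other ribosome assembly genes already seen among the rises, which were left out of the list.

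Factors that assemble ribosomes in the nucleolus formed a group not described so far. Of 93 tested, 33 rose, 0 fell and 87 had a positive change, with a median of 0.59. Among those that rose were Ppan (1.11 ± 0.12), Nop14 (1.09 ± 0.16), Wdr75 (1.06 ± 0.13, but 0.03 on its other probe set) and Nop58 (1.03 ± 0.17). The 4 array-pair medians lay between 0.47 and 0.65. The median lay at percentile 100 of 10000 random lists matched on mean level, whose highest was 0.17. Such lists do not hold genes that vary together, so this percentile may overstate how rare such a median is. Limma's camera gave an unadjusted p of 1.29e-21 at the preset correlation, and 0.0696 with an estimated correlation, which misses the threshold. Ribosome assembly genes may have risen with stimulation as a group, as a hypothesis, with a difference between dishes untested.

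Tfrc, which encodes the transferrin receptor and was picked after its values were seen, fell by 1.00 ± 0.13 (adjusted p = 0.0241), and changed by -1.31 and -1.65 on its other probe sets.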
